A study of Rattus norvegicus with 16 samples.

How the data were processed

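RNA sequencing was done on liver and epididymal fat of 8 male ZDF rats, in 4 groups of 4 libraries. Per the labels' protocols, RNA was extracted with TRIzol and RNeasy columns and libraries were made with the TruSeq V2 kit, which does not mark strand, so overlapping antisense genes cannot be told apart. Per the submitters' processing notes, CASAVA 1.8.2, TopHat and Cuffdiff were used. The genome build, annotation and tool settings are not given in the sources used here. The deposited values are FPKM (fragments scaled to transcript length and to the library's mapped fragments), with a single value per gene symbol and library, as the authors made them, per the file headers. They hold no counts, so tests for normalized values were used in place of count tests, a choice fixed for this case before the data were examined. FPKM values are shares, so a change in a few abundant genes moves the others. Some abundant genes, such as Alb and Tf in liver, are listed at exactly 0, so a 0 can be a failed estimate. Genes with near-identical copies can share reads, and unnamed models are reported as uncertain. Headers number replicates from 0 and labels from 1; the record of files per sample gave the match.

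Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment, over genes at 1 FPKM or more in at least 4 libraries of the fit. Fold changes are on this scale and understate changes of low genes. Genes passed at an adjusted p under 0.05, and between tissues also at a log2 fold change over 1 in size. Liver and fat were fitted apart, and the difference of the diet effects over 16 libraries. Both tissues came from the same rats, but the labels do not say which libraries share a rat. The main fits across tissues therefore treated the libraries as independent. Gene lists fixed before the data were examined (28 of pathways, 14 of cell types) were tested with limma's camera at a preset correlation of 0.01, where at least 3 genes were measured, with adjustment over 34 lists in liver and 38 in fat. Of the list genes, 611 matched by symbol, 32 by an older name in a RefSeq table of the GRCr8 assembly, and 37 were not matched and not used here, Fasn and Apoa1 among them. Of the 22517 symbols, 13499 are current in that table.

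The genes named were set by a rule fixed before the data were examined. For each diet comparison it took the 10 largest rises and 10 largest falls among genes that passed, did not overlap between groups and had a mean of at least 1 FPKM, without unnamed models. It also took up to 4 members with the smallest adjusted p of each list called or with a member called, and a preset of metabolic genes whatever their p. Where fewer than 5 genes passed, the 5 with the smallest p were added. The differences between tissues took the 5 smallest adjusted p and genes called in both tissues, and the tissue comparison took preset markers. The text names part of these, and some genes of the preset are not reported here.

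Exact permutation tests of a list's per-library mean used the 70 arrangements of 4 against 4 libraries. Alternatives were a pseudocount of 0.1, no filter, median centring, a replicate block, each replicate left out, all 16 libraries in one model, an adjusted p under 0.1, a fold change over 2-fold as well, an estimated correlation in camera, and the fry test. Subtraction of the liver share from fat, for the shared response also with the liver profile of the same diet, and removal of genes at 0 in a whole group, were added after seeing the data. No pair of replicates held identical values, and within groups the log2 values correlated at 0.971 to 0.994 across genes. The fit was tested on simulated data with 200 changed genes. Of changes of 1 on the log2 scale it recovered 92.5% in liver (9710 genes), 80.6% in fat (11501 genes), 70.1% for the difference between tissues (12079 genes) and 83.6% between tissues (11492 genes), with 8, 8, 5 and 10 false calls over all sizes. A list shifted on purpose was called in both tissues, with 1 other list called in liver and 0 in fat. The simulated noise was drawn for each gene alone, so these false calls do not speak for genes that move together. In the real data the interferon list in liver had an estimated correlation of 0.58 between its genes. Of changes of 0.5 the fit recovered 65.7%, 44.8%, 13.4% and 35.8%. Figures were drawn with matplotlib 3.10.9.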

Results

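Gene expression was measured by RNA sequencing in liver and epididymal fat of male Zucker diabetic fatty (fa/fa) rats, which lack a working leptin receptor and become obese and diabetic. The rats received feed with R-α-lipoic acid (LA), a sulphur-containing cofactor of mitochondrial dehydrogenase complexes, or were pair-fed (PF) without it, for 2 weeks from 9 to 11 weeks of age. Each tissue and feed gave 4 biological replicates, 16 libraries from 8 rats. The files list 22517 gene symbols in FPKM. The number of genes at 1 FPKM or more was 9522 to 9689 in PF liver, 9644 to 9738 in LA liver, 11320 to 11480 in PF fat and 11276 to 11439 in LA fat. Total read numbers are unknown, but the steps between low values show the relative depth. The value of a single fragment was 0.853 to 1 in PF liver and 0.722 to 0.895 in LA liver, relative to PF liver replicate 1, so the LA liver libraries were on the whole the deeper ones. In fat these values were 0.774 to 0.959 under PF and 0.737 to 0.865 under LA.

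The liver comparison asked which transcripts differed between LA and PF rats. Of the fixed gene lists, 14 of 16 measured interferon-response genes rose under LA, and 6 of 15 genes of de novo lipogenesis, which makes fatty acids from sugar, fell. Both list calls were lost with an estimated correlation between genes (adjusted p = 0.31 for each). The per-library means of these lists and of the macrophage, hepatocyte, lipoprotein and glycolysis lists separated the diets (two-sided exact permutation p = 0.029 for each, and 0.16 adjusted over 34 lists), of which camera did not call the glycolysis list. Mx2, an antiviral GTPase, rose from 4.92 ± 1.16 to 40.1 ± 9.35 FPKM (mean ± SD, n = 4 per group), and Pnpla3, a lipid droplet protein induced by carbohydrate feeding, fell from 181 ± 48.0 to 15.6 ± 14.7 FPKM. Of 9710 genes tested with limma, 435 passed, 220 higher and 215 lower under LA. No overlap between LA and PF libraries was seen for 425 of these and for 1192 of all tested genes, where chance gives a share of 0.0286. The count was 208 without LA replicate 2 and 267 without PF replicate 1.

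The interferon list held 16 measured genes, of which 14 rose and 2 did not pass, with a median log2 fold change of 1.69 (limma's camera, adjusted p = 3.2e-26, and adjusted p = 0.31 with an estimated correlation). Adjusted over the list alone, 15 rose. Rsad2, which blocks the budding of enveloped viruses, rose from 0.477 ± 0.0937 to 7.83 ± 2.42 FPKM (log2 fold change 2.54, SE 0.16, adjusted p = 0.000117). Isg15, a ubiquitin-like protein listed under its older symbol G1p2, rose by 2.98 on the log2 scale (SE 0.22). Irf7, the transcription factor that amplifies type I interferon production, rose from 4.58 ± 1.04 to 31.7 ± 9.54 FPKM. Usp18, which removes Isg15 from proteins, rose from 7.71 ± 1.82 to 42.0 ± 11.0 FPKM. Oasl and Oas1a, of the family of sensors of double-stranded RNA, had log2 fold changes of 2.79 and 2.31. The list passed with fry (adjusted p = 0.0018). Outside this list, the gene listed as isg12(b) rose from 249 ± 25.9 to 1209.7 ± 328 FPKM, and the chemokine Cxcl10, which interferon induces, rose from 2.11 ± 0.750 to 8.96 ± 1.89 FPKM. The macrophage marker list was higher in the same LA livers, by a mean of 0.41 on the log2 scale.

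The macrophage markers were also higher as a list, with a median log2 fold change of 0.45 over 11 genes (camera adjusted p = 6.0e-05, and adjusted p = 0.64 with an estimated correlation). Of these, 2 rose and 9 did not pass, and 7 rose when adjusted over the list alone. Clec4f, a Kupffer cell lectin, rose from 48.4 ± 4.84 to 77.0 ± 14.0 FPKM, and the scavenger receptor Cd163 rose from 5.04 ± 0.474 to 8.59 ± 2.00 FPKM. Without PF replicate 1 neither passed, and without PF replicate 2 Cd163 did not (adjusted p up to 0.052 for Clec4f and 0.058 for Cd163). Hepatocyte markers were lower as a list, by a median of -0.39 over 9 genes (camera adjusted p = 0.0015, and adjusted p = 0.65 with an estimated correlation). Among them the fibrinogen chain genes Fgg and Fga fell, by 0.50 and 0.53 on the log2 scale, and 7 genes did not pass. Adjusted over the list alone, 6 fell and 1 rose. Cyp2e1 went the other way, from 1613 ± 264 to 2127 ± 457 FPKM, and Alb and Tf, listed at 0, were not measured. Fgg and Fga lost their call without PF replicate 1 or 2 or LA replicate 2 or 3, and Fga also without LA replicate 4 (adjusted p up to 0.070 and 0.071).

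**Figure D1:**
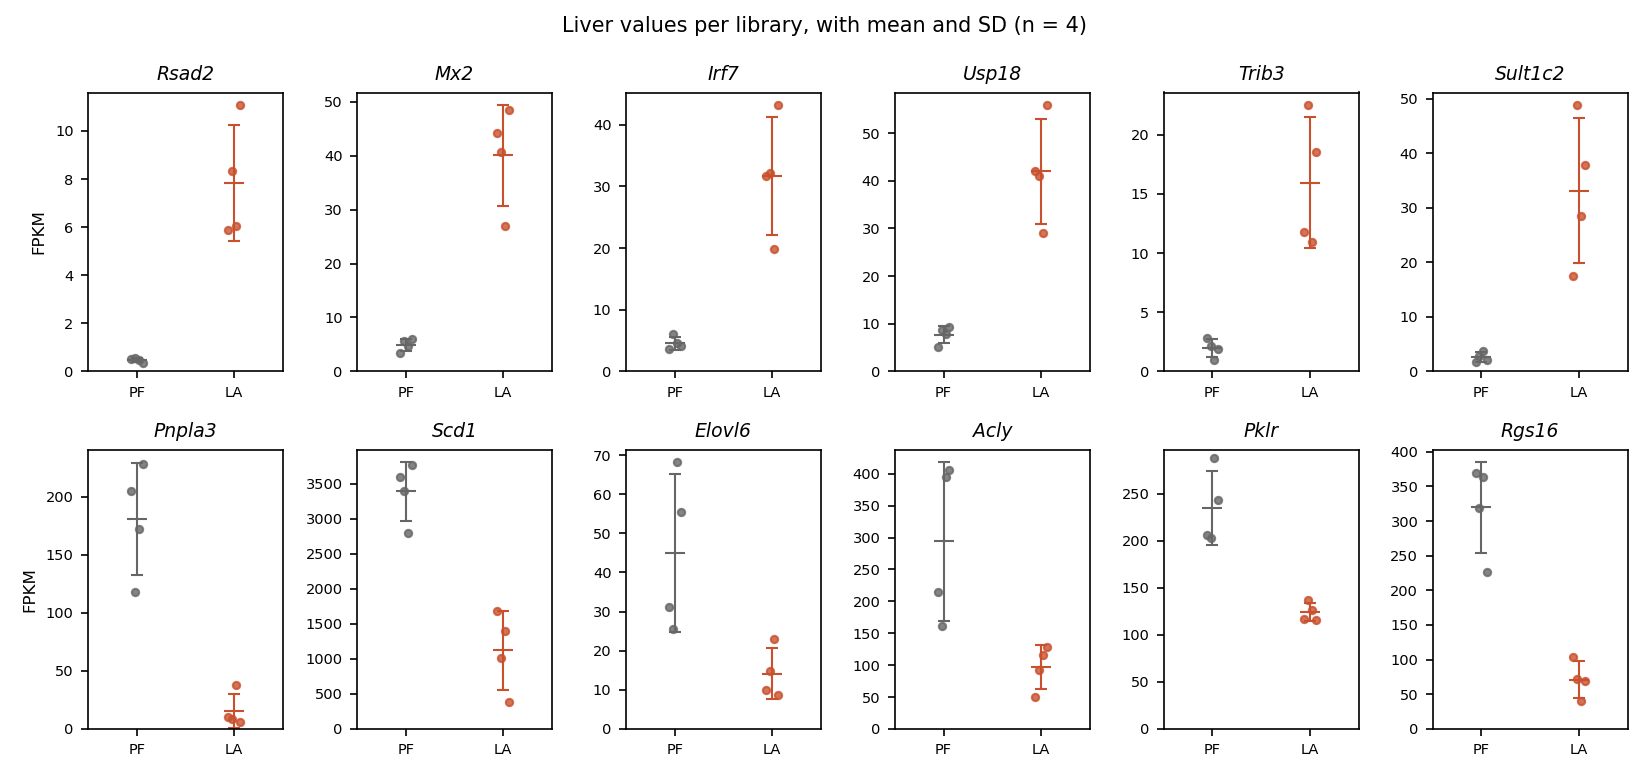
FPKM of 12 genes in the liver libraries, PF in grey and LA in red-orange, each point a library and the bars the mean with its SD over 4 libraries. Mx2 lies between 3.42 and 6.01 FPKM under PF and between 26.9 and 48.5 under LA.

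All 15 measured genes of the de novo lipogenesis list were lower under LA in the mean, with a median log2 fold change of -0.78 (camera adjusted p = 1.8e-10, and adjusted p = 0.31 with an estimated correlation). Of these, 6 fell and 9 did not pass, and 13 fell when adjusted over the list alone. Scd1, which desaturates stearate to oleate, fell from 3389.8 ± 420.2 to 1121 ± 565 FPKM (log2 fold change -1.78, SE 0.38, adjusted p = 0.025). Elovl6, which extends palmitate to stearate, fell from 45.1 ± 20.2 to 14.1 ± 6.49 FPKM. Acly, which makes cytosolic acetyl-CoA from citrate, fell from 294 ± 125 to 96.9 ± 34.2 FPKM. Scd1 did not pass without PF replicate 1, 2 or 4 or LA replicate 2 (adjusted p up to 0.067). Elovl6 did not pass without PF replicate 3 or 4 or LA replicate 1, 2 or 4 (up to 0.066), nor Acly without PF replicate 3 or 4 or LA replicate 2 (up to 0.077). With fry the list passed (adjusted p = 0.027). Besides Pnpla3, the citrate carrier Slc25a1 and the lipogenic regulator Thrsp also fell, by 0.42 and 0.79 on the log2 scale. The hepatocyte marker list was lower in the same livers, by a median of -0.39. Acaca, the acetyl-CoA carboxylase, and Srebf1, the insulin-responsive transcription factor of the pathway, had log2 fold changes of -0.89 and -0.78 with adjusted p of 0.055 and 0.13.

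Pklr, the liver pyruvate kinase, fell from 235 ± 39.5 to 124 ± 9.67 FPKM, Khk, the first enzyme of fructose use, fell by 0.60, and Aldoa rose by 0.51 on the log2 scale. These were the 3 of 17 measured members of the glycolysis list that passed, and the list itself did not (camera adjusted p = 0.16, median -0.02), although its per-library mean was lower under LA by -0.10 with no overlap between the diets (exact permutation p = 0.029, unadjusted). Aldoa did not pass without PF replicate 1, 2 or 3 or LA replicate 2 (adjusted p up to 0.071). Tkt of the pentose phosphate pathway fell from 178 ± 20.4 to 102 ± 4.59 FPKM. Rgs16, a regulator of G protein signalling, fell from 320 ± 65.7 to 71.3 ± 26.2 FPKM. Dgat2, which completes triglyceride synthesis, fell by 0.59, and the acyl-CoA synthetases Acsl5 and Acsl1 fell by 0.89 and 0.43 on the log2 scale. Their lists did not pass. In triglyceride synthesis Dgat2 was the 1 of 12 genes called, with a list median of 0.14 and mean of -0.03 (camera adjusted p = 0.97), and in fatty acid uptake Acsl5 and Acsl1 were the 2 of 12 called (median -0.05, camera adjusted p = 0.35). Dgat2 did not pass without PF replicate 3 or 4 or LA replicate 1 or 2 (adjusted p up to 0.070). Pck1 and G6pc, enzymes of glucose production, had log2 fold changes of 0.03 and -0.02, with adjusted p of 0.97 and 0.98.

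The fatty acid oxidation list was higher, with a median log2 fold change of 0.10 over 30 genes (camera adjusted p = 0.031, and adjusted p = 0.71 with an estimated correlation). Of these, 5 rose, 1 fell and 24 did not pass, and adjusted over the list alone 10 rose and 3 fell. The median was 0.17 without LA replicate 1 and 0.03 without LA replicate 4, the highest and lowest over the alternatives, and the per-library mean had an exact permutation p of 0.057, unadjusted. The list did not pass without PF replicate 1 or 3 or LA replicate 4 (adjusted p of 0.087, 0.074 and 0.17). Acot2, a mitochondrial acyl-CoA thioesterase, rose from 6.14 ± 0.333 to 26.2 ± 12.1 FPKM, and Vnn1, a pantetheinase regulated by PPARα, rose from 5.86 ± 1.05 to 12.9 ± 3.05 FPKM. Cyp4a10 and Cyp4a3, fatty acid omega-hydroxylases, rose by 0.49 and 0.47 on the log2 scale. Slc25a20, the carnitine carrier, rose by 0.31, while Hadh of the beta-oxidation cycle fell by 0.44, and both were named after their values were seen. Cpt1a and Fgf21 had log2 fold changes of 0.17 and 1.09 with adjusted p of 0.64 and 0.16.

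Apolipoprotein and lipoprotein assembly genes were lower as a list, with a median of -0.27 over 12 genes (camera adjusted p = 0.0010, and adjusted p = 0.64 with an estimated correlation). The hepatocyte markers were lower in the same livers by a median of -0.39. Apoa4 fell from 2293 ± 286 to 1096 ± 82.4 FPKM, Apoc2 and Tm6sf2 fell by 0.50 and 0.52 on the log2 scale, and 9 genes did not pass; adjusted over the list alone 5 fell. Apoc2 passed only without LA replicate 4 among fits with 1 library left out, and Tm6sf2 only without PF or LA replicate 4 (adjusted p up to 0.094 and 0.10). The cholesterol synthesis list was lower, by a median of -0.32 over 23 genes (camera adjusted p = 0.0018, and adjusted p = 0.71 with an estimated correlation), with no member past limma's gene test, and did not pass without PF replicate 4 (median -0.20, adjusted p = 0.075). Its median was -0.21 without LA replicate 2, and its per-library mean had an exact permutation p of 0.29, unadjusted. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of -0.35 with an adjusted p of 0.59. The clock list was lower by a median of -0.25 over 14 genes (camera adjusted p = 0.0056, and adjusted p = 0.64 with an estimated correlation), with Nr1d1 and Bhlhe40 as the 2 that fell, and 4 that fell when adjusted over the list alone. Its median was -0.16 without LA replicate 4. With all libraries kept, its per-library mean had an exact permutation p of 0.057, unadjusted. Bhlhe40 passed only without PF replicate 1 or 3 among fits with 1 library left out (adjusted p up to 0.10). Nr1d1, the repressor Rev-erbα, fell from 32.3 ± 1.55 to 19.6 ± 3.53 FPKM.

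Genes of the lipoate-dependent complexes and their regulators were lower as a list, by a median of -0.13 over 17 genes (camera adjusted p = 0.022, and adjusted p = 0.65 with an estimated correlation). Pdk1, a kinase that inactivates pyruvate dehydrogenase, fell from 52.6 ± 8.46 to 28.9 ± 3.82 FPKM, Ogdh, a subunit of 2-oxoglutarate dehydrogenase, rose from 31.8 ± 1.73 to 39.5 ± 1.70 FPKM, and 15 genes did not pass; adjusted over the list alone 1 rose and 4 fell. The list did not pass without PF replicate 3 or 4 or LA replicate 1 (adjusted p of 0.067, 0.072 and 0.086), its median was -0.20 without LA replicate 4 and its exact permutation p 0.057, unadjusted. In the same livers the hepatocyte markers were lower by a larger median, -0.39, and the macrophage markers higher by 0.45. Ogdh passed only without PF replicate 3 (up to 0.10). The list of NRF2 targets did not pass (camera adjusted p = 0.10), but of its 20 genes 4 rose and 1, Tkt, fell. Gstp1, a glutathione transferase, rose from 18.7 ± 1.88 to 47.1 ± 16.8 FPKM, Srxn1 and Gclm rose by 0.72 and 0.44 on the log2 scale, and the transporter Abcc4, named after its values were seen, rose by 0.51. Gstp1 passed only without PF replicate 4 or LA replicate 1, and Gclm only without PF replicate 1 or LA replicate 4 (adjusted p up to 0.065 and 0.076). Trib3, a stress-induced pseudokinase that binds AKT, rose from 1.95 ± 0.756 to 15.9 ± 5.54 FPKM. Sult1c2, a sulphotransferase, rose from 2.58 ± 0.923 to 33.1 ± 13.3 FPKM, a log2 fold change of 3.20 (SE 0.28, adjusted p = 0.000283).

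**Figure D2:**
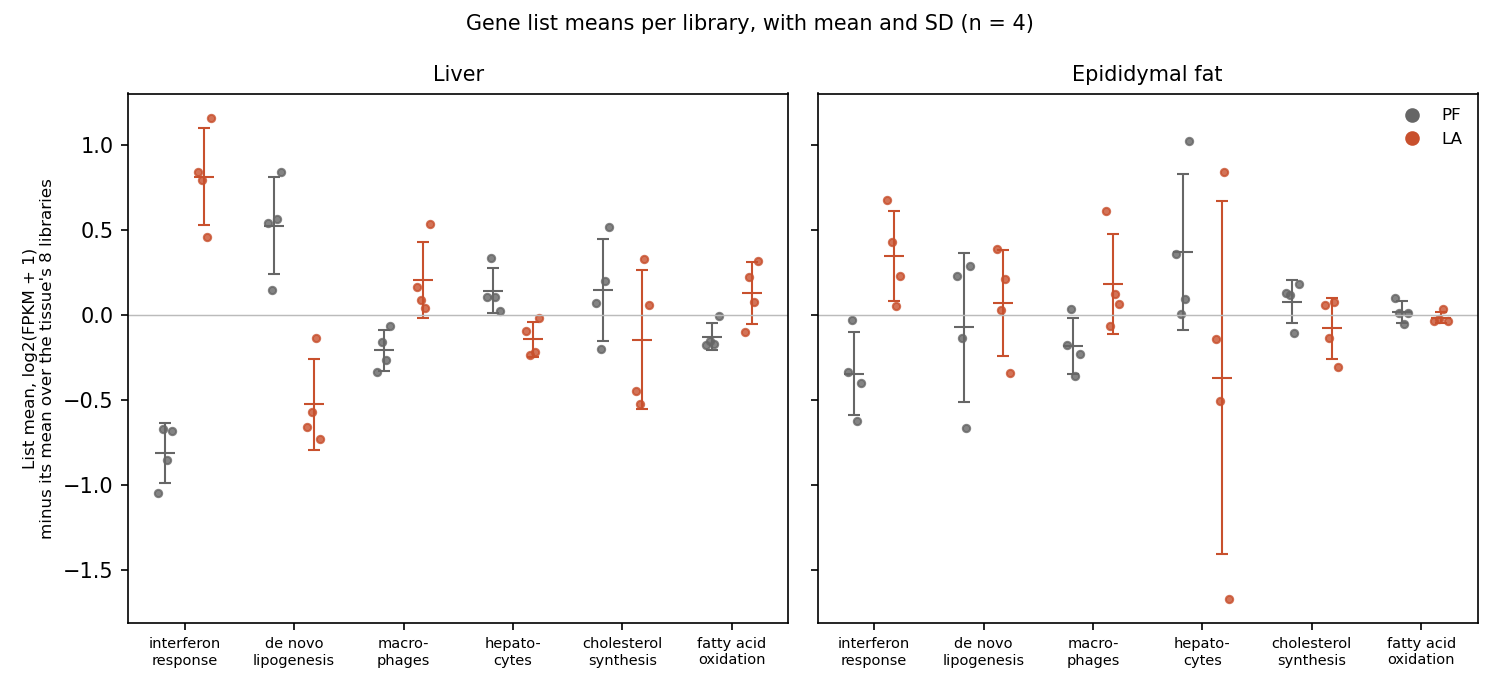
Mean log2(FPKM + 1) of 6 gene lists in each library, centred on the mean of the tissue's 8 libraries, PF in grey and LA in red-orange, with the mean and SD over 4 libraries. The interferon list separates LA from PF in both tissues, by 1.63 in liver and 0.69 in fat, and the lipogenesis mean in fat includes Scd1, listed at 0 in the PF libraries.

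In epididymal fat the same comparison found Scd1 higher and an unnamed model lower under LA, and each rests on values near or at 0 in a group. Scd1 was listed at 0 in all 4 PF fat libraries and at 3477, 1123, 1661 and 407 FPKM in the LA fat libraries. The unnamed model LOC100359973 was at 9.36, 9.43, 7.68 and 15.3 FPKM under PF and at 1.30, 0.554, 0.630 and 0 under LA, and at 1284 ± 131 FPKM in PF liver. These were the 2 of 11501 genes that passed with limma, and 451 had an unadjusted p under 0.05 where chance alone gives 575. The count was 1 without PF replicate 2, LA replicate 1 or LA replicate 4 and 0 without LA replicate 2 or 3. Scd1 passed without each PF replicate, and without any LA replicate it had values in only 3 libraries and was below the filter, so it was not tested. LOC100359973 was tested in each case and did not pass without PF replicate 2, LA replicate 2 or LA replicate 3 (adjusted p up to 0.096). The next smallest p belonged to LOC100360859 and LOC100363391, with adjusted p of 0.17 for both, and to Ifit3 with an adjusted p of 0.35, none of which passed.

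Interferon-response genes in fat were higher as a list, with each of 16 measured genes higher in the mean under LA and a median log2 fold change of 0.71 (camera adjusted p = 1.2e-22, and adjusted p = 0.43 with an estimated correlation). No single member passed limma's test over all genes, and 13 rose when adjusted over the list alone. Mx2 was at 5.84 ± 1.96 FPKM under PF and 15.6 ± 4.33 under LA, Mx1 at 3.61 ± 0.977 and 9.56 ± 2.70, and Ifit3 at 6.06 ± 0.771 and 12.8 ± 2.93. The per-library mean of the list was higher under LA by 0.69 (two-sided exact permutation p = 0.029, the smallest that 4 against 4 allows, and 0.54 adjusted over 38 lists). In liver the same difference was 1.63 with the same exact p, and 0.16 adjusted over 34 lists. The liver and fat libraries came from the same rats, so these results are not independent.

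Macrophage markers in fat were higher as a list, by a median of 0.25 over 13 genes (camera adjusted p = 1.7e-08, and adjusted p = 0.44 with an estimated correlation). All 13 were higher in the mean, none passed limma's test over all genes, and 3 rose when adjusted over the list alone. Itgax, a marker of inflammatory macrophages of fat, was at 2.43 ± 0.698 FPKM under PF and 5.13 ± 2.08 under LA. Gpnmb, of lipid-laden macrophages, was at 96.5 ± 16.9 and 181 ± 77.8 FPKM, and Cd68 at 66.7 ± 9.96 and 93.9 ± 31.9. LA replicate 1 held the highest values, with Gpnmb at 295 FPKM against 127, 169 and 134 in LA replicates 2, 3 and 4, and Cd68 at 140.0 against 73.3, 90.7 and 71.6. The per-library mean of the list was 0.61, -0.06, 0.12 and 0.06 in LA replicates 1 to 4 and -0.18, 0.03, -0.36 and -0.23 in PF replicates 1 to 4 (two-sided exact permutation p = 0.057, unadjusted). Without LA replicate 1 the list median was 0.17 and the list passed (camera adjusted p = 4.8e-05). The de novo lipogenesis list had a median of -0.54 over 15 genes (camera adjusted p = 3.0e-06, and adjusted p = 0.44 with an estimated correlation), while its mean was 0.14 with Scd1 included. Its median was -0.34 without PF replicate 4, and its per-library mean had an exact permutation p of 0.63, unadjusted. That mean includes Scd1, listed at 0 under PF, and was not tested without it. The p of 0.63 therefore does not speak for the other genes. In the list 13 genes were lower and 2 higher in the mean under LA. Of the 15, Scd1 rose and 14 did not pass. Elovl6 was at 8.97 ± 4.24 and 3.69 ± 0.607 FPKM, and Pnpla3 at 103 ± 39.1 and 46.1 ± 16.5.

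Oxidative phosphorylation genes were lower as a list by a median of -0.17 over 25 genes (camera adjusted p = 3.0e-06, and adjusted p = 0.58 with an estimated correlation), with none of the 25 past the gene test, and lipoate-dependent enzymes by -0.15 over 20, none past it (camera adjusted p = 8.8e-05, and adjusted p = 0.44 with an estimated correlation). The per-library mean of the oxidative phosphorylation list overlapped between the diets (two-sided exact permutation p = 0.31). It stood at 0.14, 0.22, -0.29 and 0.26 in PF replicates 1 to 4 and at 0.14, -0.24, 0.04 and -0.27 in LA replicates 1 to 4, on the log2 scale relative to the mean of the 8 libraries. Its median was -0.29 and -0.11 without PF replicate 3 and 4, and -0.11 and -0.09 without LA replicate 2 and 4. The lipoate median was -0.08 without PF replicate 1. With all libraries kept, the per-library mean of the lipoate list had an exact permutation p of 0.14, unadjusted. The adipocyte identity list had a median of -0.11 over 18 genes (camera adjusted p = 0.0026, and adjusted p = 0.43 with an estimated correlation, with an exact permutation p of 0.029, unadjusted). In it the insulin-responsive glucose transporter Slc2a4 was at 39.5 ± 6.35 FPKM under PF and 29.0 ± 2.92 under LA, and the adrenergic receptor Adrb3 at 24.0 ± 3.71 and 14.6 ± 4.08. Lpl, which releases fatty acids from lipoproteins, was at 3342 ± 723 and 2228 ± 304 FPKM. Leptin was at 1610.3 ± 343 and 1624 ± 389 FPKM, adiponectin (Adipoq) at 5469.7 ± 189 and 5242 ± 253, Pparg at 113 ± 24.6 and 98.1 ± 12.9, Pnpla2 at 724 ± 106 and 808 ± 78.2, and Ccl2 at 39.9 ± 14.1 and 50.7 ± 28.2, none past the test. Lists that did not pass included the adipocyte markers (median -0.01, camera adjusted p = 0.84), lipolysis (-0.06, 0.44), fatty acid oxidation (-0.06, 0.14) and fatty acid uptake (median 0.03 and mean -0.09, 0.50). Ucp1 was below the filter, with 0.0782 FPKM as its highest value.

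The other lists called in fat had no member past the gene test. Cholesterol synthesis was lower by a median of -0.13 (22 genes, camera adjusted p = 8.8e-05, and adjusted p = 0.44 with an estimated correlation) and glycolysis by -0.15 (19 genes, 0.0023, and adjusted p = 0.54 with an estimated correlation). The per-library means of both overlapped between the diets (two-sided exact permutation p = 0.17 and 0.34, unadjusted). Relative to the mean of the 8 libraries, cholesterol synthesis stood at 0.13, 0.11, -0.11 and 0.18 in PF replicates 1 to 4 and at 0.06, -0.14, 0.07 and -0.31 in LA replicates 1 to 4. Glycolysis stood at 0.19, 0.08, -0.19 and 0.19 under PF and at 0.11, -0.11, 0.05 and -0.32 under LA. The cholesterol median was -0.21 without PF replicate 3, -0.19 without LA replicate 3 and -0.06 without LA replicate 4. The glycolysis median was -0.27 without PF replicate 3, and the list did not pass without LA replicate 4 (median -0.09, adjusted p = 0.14). Glycogen metabolism was lower by -0.14 (11 genes, camera adjusted p = 0.0026, and adjusted p = 0.43 with an estimated correlation), and by -0.21 without PF replicate 3. Triglyceride synthesis was lower by -0.11 (13 genes, 0.0026, and adjusted p = 0.44 with an estimated correlation), by -0.07 without PF replicate 1, and did not pass without LA replicate 4 (adjusted p = 0.058). Both had an exact permutation p of 0.086, unadjusted.

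The adipokine list in fat was lower by -0.11 (10 genes, camera adjusted p = 0.016, and adjusted p = 0.44 with an estimated correlation), with 1 that rose and 2 that fell adjusted over the list alone, and did not pass without PF replicate 2 or LA replicate 4 (0.088 and 0.091). Its median was -0.25 and -0.06 without PF replicate 3 and 4, and -0.22 and -0.17 without LA replicate 1 and 3. Thermogenic genes were lower by -0.14 (8 genes, 0.033, and adjusted p = 0.43 with an estimated correlation) but not without PF replicate 1 or 2 or LA replicate 3 or 4 (adjusted p up to 0.14). Their median was -0.09 and -0.22 without PF replicate 2 and 3, and -0.06 without LA replicate 4. Endothelial markers were lower by -0.12 (9 genes, 0.025, and adjusted p = 0.54 with an estimated correlation) but not without PF replicate 1, 2 or 3 or LA replicate 1 or 3 (up to 0.26). Their median turned to 0.01 without LA replicate 3, was -0.02, -0.03 and -0.22 without PF replicate 1, 3 and 4, and -0.02, -0.21 and -0.18 without LA replicate 1, 2 and 4. With no filter on low values the thermogenic and endothelial medians were both -0.03. Unfolded protein response genes were higher by 0.13 (18 genes, 0.023, and adjusted p = 0.60 with an estimated correlation) but not without PF replicate 3 or LA replicate 1 or 3 (up to 0.51). Their median was 0.20 without PF replicate 2 or LA replicate 4 and 0.04 without LA replicate 1. The exact permutation p of the per-library means was 0.11, 0.086, 0.26 and 0.31 for these 4 lists, unadjusted.

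Hepatocyte markers were present in the fat libraries and lower under LA, by a median of -0.81 over 11 genes (camera adjusted p = 2.0e-06, and adjusted p = 0.44 with an estimated correlation). Amino acid catabolism genes were lower by -0.31 over 20 genes (camera adjusted p = 0.00059, and adjusted p = 0.58 with an estimated correlation) and lipoprotein genes by -0.26 over 11 (0.0023, and adjusted p = 0.49 with an estimated correlation), none past the gene test. Neither list passed without PF replicate 4 (adjusted p of 0.14 and 0.075) or LA replicate 4 (0.19 and 0.18). The hepatocyte median was -1.26 without LA replicate 3 and -0.32 without LA replicate 4. The amino acid median was -0.19 without PF replicate 4, -0.52 and -0.13 without LA replicate 3 and 4, and -0.54 with a pseudocount of 0.1, and the lipoprotein median -0.43 without PF replicate 2 and -0.44 and -0.12 without LA replicate 3 and 4. The exact permutation p was 0.23, 0.31 and 0.40 for these 3 lists, unadjusted. Liver-abundant genes were those with a mean of at least 1000 FPKM in liver that was at least 20 times their mean in fat. Over these 54 genes, fat values stood at a median of 0.592%, 0.433%, 0.517% and 1.02% of the mean liver value in the PF libraries and 0.411%, 0.295%, 0.891% and 0.101% in the LA libraries. With this share of the liver profile subtracted, an alternative chosen after seeing the data, the hepatocyte, amino acid catabolism and lipoprotein list calls ended, and LOC100359973 was below the filter and no longer tested. The median of the hepatocyte list was then 0.00, and 14 of the 17 lists called in fat kept their call. Members of the 3 lists that lost it, such as Ttr, Ass1 and Apoc2, were among the 54 genes. That loss therefore follows in part from how the share was set.

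**Figure D3:**
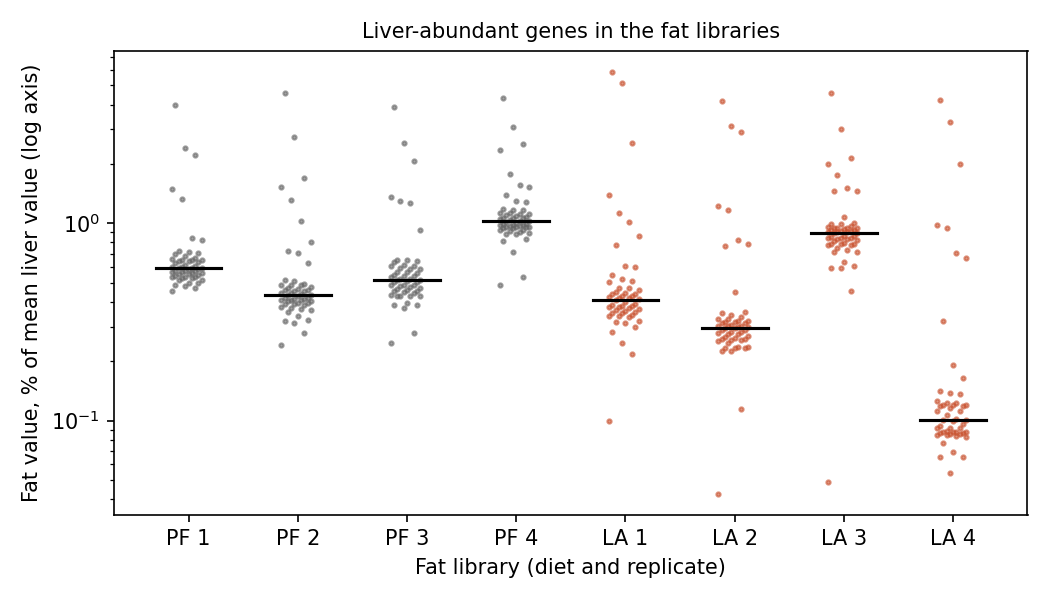
Values of 54 liver-abundant genes in each fat library, as a percentage of their mean liver value on a log axis, PF in grey and LA in red-orange, with the median as a black line. Medians run from 0.101% in LA replicate 4, where 2 genes at 0 are not drawn, to 1.02% in PF replicate 4.

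Whether the response to LA differed between the tissues was tested directly, as the liver effect minus the fat effect over 16 libraries. Of 12079 genes, 46 passed, 28 with a higher and 18 with a lower effect in liver. As many passed in 6 of 100 drawn splits of the libraries, the real one included, so chance is not excluded for this count. After Scd1, the smallest adjusted p belonged to RGD1562392, an unnamed model at 0.879 ± 0.391 FPKM in PF liver and 12.5 ± 3.66 in LA liver and near 0 in fat, with a difference of 2.87 on the log2 scale (SE 0.25). Sult1c2 followed with 3.28 (SE 0.33) and LOC100359973 with 2.87. In PF and LA fat Sult1c2 was at 0.132 and 0.0622 FPKM, so its difference restates the liver change. LOC100359973 was at 1284 and 1310 FPKM in PF and LA liver, so its difference rests on its fat values, which are in doubt. Cml2 rose in liver from 5.56 ± 1.53 to 16.6 ± 1.19 FPKM, with a difference between tissues of 1.57 (SE 0.19, adjusted p = 0.000902). Cml2 was also near 0 in fat, at 0.118 and 0.0232 FPKM under PF and LA. Of 365 genes called in liver and tested in fat, 1 was also called in fat, Scd1. The count of 46 was 19, 24 and 28 without fat PF replicate 1, 2 and 4, 30 and 28 without fat LA replicate 2 and 4, 22 without liver PF replicate 1 and 24 without liver LA replicate 2.

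The tissue comparison in PF rats checked the labels and gave the background of each tissue. Ttr, the hepatic thyroxine carrier, was at 21245 ± 2997 FPKM in liver and 117 ± 43.9 in fat, and Cyp2e1 at 1613 ± 264 and 12.0 ± 4.82. Cfd (adipsin) was at 9.77 ± 2.75 FPKM in liver and 1208 ± 82.2 in fat. Adiponectin, leptin and perilipin (listed as Plin) were listed at 0 in each liver library, and Plin was at 620.1, 540.2, 596 and 479 FPKM in the PF fat libraries. Albumin (Alb) was also listed at 0 in each liver library and at 355, 245, 290.3 and 581 FPKM in the PF fat libraries, so its value in liver cannot be read as its abundance. The log2 difference was 7.55 (SE 0.23) for Ttr, 7.01 (SE 0.23) for Cyp2e1 and -6.84 (SE 0.15) for Cfd. Ttr and Cyp2e1 were among the 54 liver-abundant genes that set the liver share. Their values in fat, and so these differences, may reflect carried-over liver RNA rather than expression in fat. Of 11492 genes, 5447 differed by more than 2-fold, 1273 higher in liver and 4174 higher in fat. The number higher in fat was 2670, 2659, 2693 and 2681 without fat PF replicate 1, 2, 3 and 4, since genes seen only in fat then fell short of the 4 libraries of the filter and 9823 to 9826 genes were tested. The median gene stood at -0.66 on the log2 scale, and after centring each library on its median the split was 2064 to 2253.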

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

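The tests of carried-over liver RNA, of its share by diet, of the interferon list and of the values at 0 were chosen after the results were seen, and the macrophage test was split by tissue after a joint test gave an exact permutation p of 0.057; the tests over other splits of the samples were set before.

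Liver transcripts appeared in each fat library. At least 81.5% of 54 liver-abundant genes lay within 2-fold of their library's median share of the liver level. Liver RNA carried into the fat libraries would give this, but the bound of the test was set after the near-constant ratios had been seen. The 54 genes were also chosen for a liver mean at least 20 times the fat mean. That choice left out liver-abundant genes with more RNA in fat and favours a steady ratio. A diet effect on this share stays open (exact permutation p = 0.26). The lists of hepatocyte, amino acid catabolism and lipoprotein genes lost their calls in fat when the share was subtracted. Members of each list were among the 54 genes that set the share, so this loss is not separate support for carried-over RNA.

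The interferon list was higher under LA in both tissues. In fat the median log2 fold change was 0.72 after the share was subtracted. That subtraction used the mean liver profile of both diets, so it could not remove a rise particular to LA liver. The share was at most 0.891% in LA fat. Mx2, Mx1 and Ifit3 were at means of 40.1, 5.67 and 12.1 FPKM in LA liver and 15.6, 9.56 and 12.8 in LA fat. For these genes the values argue against carried-over liver RNA as the cause in fat. More macrophages alone are argued against in liver, where the list rose beyond the macrophage list (difference 1.21, exact permutation p = 0.029), but stay open in fat (difference 0.33, exact permutation p = 0.057); interferon activity within those cells was not tested. The feed itself stays open (exact permutation p = 0.029 in each tissue), since the labels do not tell cage or exposure apart from diet. Both tissues came from the same rats, so these values are not independent of each other.

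Scd1 and LOC100359973 were the 2 genes called in fat. The liver share alone would put Scd1 at 9.76 FPKM or more in each PF fat library, against the listed 0, which argues against a true absence. Values that failed for whole groups of libraries are a candidate explanation. In all, 16 genes were listed at 0 in every liver library and at 10 FPKM or more in every fat library, Alb among them. Others of these, such as Adipoq, Lep and Retn, are fat genes that liver may truly lack. They were at 0 under both diets, whereas Scd1 was at 0 in fat under PF only. Removing genes at 0 in a whole diet group of fat left 11500 of 11501 tested genes, so no other gene there paralleled Scd1. LOC100359973 was at 1.14 to 1.68 times its liver-share level in PF fat, near what carried-over RNA alone would give. It was itself among the 54 genes that set the share, so a value near that level is partly built in. In LA fat it was at no more than 0.244 of that level, which argues against that RNA as the whole cause. For LOC100359973, reads assigned to another copy were not tested. Its log2 fold change of -2.84 (SE 0.26) has no counterpart after the share was subtracted, since it was then at 1.67, 3.82, 0.971 and 2.05 FPKM under PF and 0 in each LA library, and its call ended because it was below the filter.

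The 435 genes called in liver came from 1 of 35 splits of the libraries, with at most 0 in the others. The 5447 between tissues did likewise, with at most 0. The other splits mixed the groups, so a real difference widened the spread within each side and made calls there unlikely. The smallest share that these splits allow is 1 of 35, so this test alone does not exclude chance for either count. Nor is it excluded for the remaining counts, which other splits reached. As many calls came from 2 of 35 splits for the 9 lists in liver (the highest other 10) and from 4 of 35 for the 17 lists in fat (the highest other 20). For the 2 genes in fat it was 2 of 35 (the highest other 2380). For the 46 genes that differed between tissues it was 6 of 100 drawn splits (the highest other 1059). The split of fat with 2380 genes set PF replicates 1 and 3 with LA replicates 2 and 4 against the rest, which points to a structure of the fat libraries other than diet. The oxidative phosphorylation, glycolysis and cholesterol synthesis means in fat were lowest in PF replicate 3 and LA replicates 2 and 4. They were not low in PF replicate 1. Whether that structure accounts for these list calls was not tested.

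A single library stood far from the other 3 of its group in 26 of 557 checks, where chance gives about 1 in 20, or 28. In liver under PF these were Baat at 581 FPKM, Cd163 at 5.75 and the fatty acid oxidation mean at -0.0067 in replicate 4, Cfd at 13.9, Tek at 2.83, Tfrc at 9.15 and Ttr at 25679 in replicate 2, and Cyp4a3 at 114 in replicate 3. In liver under LA they were Cyp3a9 at 78.7, Gpd1 at 335, Ogdh at 42.0 and Srebf1 at 186 FPKM in replicate 2, Cyp7a1 at 183, Dlat at 19.7 and Pnpla3 at 37.5 in replicate 3, and Klf15 at 42.3 and Tfrc at 13.9 in replicate 1. In fat under PF they were Apoc1 at 88.0, Apoh at 36.2, Ucp1 at 0.0782 and the lipoprotein mean at 0.60 in replicate 4, and Atp5b at 1122 and the adipokine mean at -0.17 in replicate 3. In fat under LA they were Atf3 at 39.1 FPKM in replicate 1, Cml2 at 0.0927 in replicate 2 and RGD1562392 at 0.0846 in replicate 3.

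The effect of LA differed between liver and fat, by the test of the difference itself, for 11 of the named genes, though chance is not excluded for the count they belong to. On the log2 scale the liver effect minus the fat effect was 3.28 for Sult1c2, 2.87 for RGD1562392, 2.04 for Rsad2, 1.91 for Trib3, 1.81 for Acot2, 1.57 for Cml2 and -1.02 for Acsl5. It was 2.87 for LOC100359973, 2.54 for LOC100360859, 2.27 for LOC100363391 and -12.10 for Scd1, whose fat values are in doubt. Several of these genes were near 0 in a tissue, so the difference restates the other tissue's change: in PF and LA fat Sult1c2 was at 0.132 and 0.0622 FPKM, Cml2 at 0.118 and 0.0232 and RGD1562392 at 0.0563 and 0.0212, and in LA liver LOC100360859 was at 0.446 and LOC100363391 at 0.239.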

How the results depend on the processing

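Count-based alternatives were not run, since the files hold no counts; subtraction of the liver share and removal of genes at 0 in a whole group were chosen after seeing the data. The cause of each difference was not tested unless fewer genes or libraries explain it. The 435 liver genes became 848 at an adjusted p under 0.1 and 68 over 2-fold as well, with 208 to 404 when a replicate was left out. The 2 fat genes became 1 with a pseudocount of 0.1, 1 with the liver share subtracted, 1 without genes at 0 in a whole group, 7 in a model of all 16 libraries and 0 to 2 when a replicate was left out. The 46 genes that differed between tissues became 22 with no filter, 94 at an adjusted p under 0.1, 25 over 2-fold as well and 19 to 60 when a replicate was left out. The 9 lists in liver became 0 with an estimated correlation and 2 with fry, which tests each list on its own, and the 17 lists in fat became 0 and 0. The cell cycle list in fat ranged from a median of -0.18 without PF replicate 4 to 0.20 without PF replicate 2, where it turned direction, and the amino acid list in fat turned to 0.16 with the liver share subtracted. The median of the lipoprotein list, no longer called, also turned (0.11), as did those of bile acid (0.07), gluconeogenesis (0.05), xenobiotic (0.12) and NRF2 (0.01) lists and that of the hepatocyte list (0.00), none past the test after it. Of 60 named genes called in liver, 32 kept their call in each leave-one-out fit in which they were tested, and 28 lost it in some. No named gene turned direction that passed before or after the change. Among those that passed in neither, G6pc and Pck1 in liver reached 0.32 and -0.26 and Lep and Ccl2 in fat -0.13 and -0.06 when a replicate was left out, against the sign of their values above. Deviations of same-numbered libraries correlated at -0.43 to 0.29, over 0.1 in 4 of 16 pairs. These were liver with fat for PF replicates 2 and 3 (0.29 and 0.12) and LA replicate 2 (0.11). The remaining pair was LA with PF liver of replicate 1 (0.15), from different rats. Weak correlations cannot show which liver and fat libraries came from the same rat. With the replicate block 476 genes passed in liver, 1 in fat, 37 between the tissues' responses and 5447 between tissues, and 10 and 19 lists. Unknown depth limits what can be said of genes near 1 FPKM.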

Other observations

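The tests of the shared response were set before their results were seen, except that subtracting the liver share from them was chosen after seeing the data, and the 4 genes named first were chosen after. Among genes outside the fixed lists, chosen after their values were seen, Akr7a3, an aldo-keto reductase of aldehyde detoxification, rose in LA liver from 42.7 ± 8.68 to 168 ± 39.3 FPKM (log2 fold change 1.94, SE 0.19, adjusted p = 0.00045). Phgdh, the first enzyme of serine synthesis, rose in liver from 0.165 ± 0.119 to 3.18 ± 1.85 FPKM (adjusted p = 0.0055) and was at 80.4 ± 12.7 and 68.0 ± 4.00 FPKM in PF and LA fat. Cabc1, needed for coenzyme Q synthesis, fell in liver from 127 ± 19.8 to 65.5 ± 1.91 FPKM (adjusted p = 0.00096), and Polg2, a subunit of the mitochondrial DNA polymerase, from 18.8 ± 1.48 to 9.76 ± 0.808 FPKM (adjusted p = 0.00045).

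A hypothesis was that the liver response to LA is shared by fat below the threshold for single genes. The 192 genes called higher in liver had a mean fat log2 fold change of 0.19, and the 172 called lower, Scd1 left out, of -0.17, a difference of 0.37 (exact permutation p = 0.057). Without the interferon list the difference was 0.32 (exact permutation p = 0.086). Liver RNA carried into the fat libraries enters these means, since its share was lower on average in LA fat (log2 difference -0.91, exact permutation p = 0.26). With the share subtracted from the same genes the difference was 0.29 (exact permutation p = 0.029) using the mean liver profile and 0.21 (exact permutation p = 0.086) using that of the same diet, and without the interferon list 0.24 and 0.17 (exact permutation p = 0.057 and 0.11). The mean of the genes called lower was then -0.08 and -0.03. A shared response may exist but is not shown, and the part that carried-over RNA contributes stays open.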
